A study of Oryza sativa Japonica Group with 30 samples.

How the data were processed

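Total RNA from rice caryopses was sequenced in 30 samples, 3 in each of 10 groups of genotype and growing condition, assigned from the sample titles. Per the submitters' processing notes, the authors used CASAVA 1.7, HISAT2 2.0.5 and DESeq2. The read counter, genome build and gene annotation are not given in the sources used here. The gene identifiers have the LOC_Os form, from which the chromosome was read, and no coordinates are given. The strand setting of the counting is not given either, so reads of overlapping and antisense genes may not be told apart.

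The 8 tables received were each named for 1 transgenic line against the wild type under 1 condition. All 8 were identical byte for byte. Per the file headers, each held a gene identifier and a baseMean, the name that DESeq2 gives to the mean over samples of counts divided by size factors. This unit is treated as a signal deposited by the authors: a pooled mean normalised count, with no sample, group, error or test. The planned tests of genotype, heat and their interaction need values per sample or a comparison table and were therefore not run, and neither were the tests of gene lists and of overlapping calls that rest on them. No column of per-sample values was left aside.

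Gene lists were fixed before the data were examined. Of 17 lists, 2 (cell division and antioxidant enzymes) were defined only by product descriptions, which the values analysed here do not carry, and were not evaluated. The description-based part of the other lists was not used either, so the prolamins are not covered. The lists held 107 locus identifiers paired with symbols from general knowledge of rice gene nomenclature, not from a source file, since neither the tables nor the reference pair the LOC_Os identifiers with names: 0 of the 39387 genes of the RefSeq table for assembly ASM3414082v1 carry such an identifier. As a check, each symbol was sought in that table, and its chromosome and relative place along it (within 0.1 of the chromosome) were compared with those of the locus. Of the 107 loci, 53 matched, 52 had no symbol in the table and 1 was contradicted and left out. Those with no symbol include ONAC127, ONAC129 and the study's targets EATB, MSR2, MST6 and bHLH144. They also include highly read genes such as BT1-1, SSIIa, BEI and GluC1. Their identities rest on general knowledge alone. This check was chosen after seeing the data: a first one, which compared gene ranks along the chromosome within 0.05, contradicted 11 loci and was replaced. The pullulanase locus is not analysed here, and HCI1, a further target named by the study, was left out because its locus was in doubt, which leaves 104 loci.

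The rule for named genes took the manipulated genes, the study's targets, members of lists of 10 or fewer genes and, in longer lists, the members with the smallest adjusted p. With no p, the members named from the starch and sugar lists were chosen after their values were seen, as the highest, the lowest and the members of shared enzyme families. LOC_Os05g41970 was also named after its value was seen. The members of the glutelin list were named as well. Each list median was compared with the medians of 10000 random lists of the same size, and the 95th percentile was set as the mark after the percentiles were seen.

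The worth of 1 read in each library was recovered from the lowest values, as those that are not sums of smaller steps within 1e-11, and the size factor was taken as the inverse of the step times 30. All 7402 values above 0 and below 0.15 were then written as a sum of whole reads (at most 8) over the 30 libraries in exactly 1 way, within 2e-15. On simulated pooled means of 8000 genes with known size factors, all 30 steps were found, and the reads per library were recovered for all genes with 1 to 5 reads (3454 with groups of 3 planted, 4171 without). In these simulations the upper bound on the values searched for steps was set from the known lowest size factor. The libraries found in the data carry no label, and none was assigned to a sample. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.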

Results

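RNA was sequenced from whole unripe rice caryopses (the developing grain with its fruit coat) collected 7 days after pollination. The 30 samples fell into 10 groups of 3: 5 genotypes, each grown under 2 field conditions. The genotypes were the wild type ZH11, lines overexpressing ONAC127 or ONAC129, and mutant lines of either gene. ONAC127 and ONAC129 encode NAC transcription factors. Heat-stressed plants spent about 6 h a day above 35 °C, with peaks near 40 °C. Plants under normal cultivation had 3 days above that temperature and a mean daytime temperature of about 30 °C. The labels do not say whether the 3 samples of a group came from separate plants.

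The design asks which genes differ from the wild type in each transgenic line under each condition (8 comparisons), which genes differ between hot and normal conditions within each genotype (5 comparisons), and whether a genotype's effect differs between conditions (4 comparisons). None of these was computed. The values analysed here were 1 pooled mean of normalised read counts per gene, and the 8 tables named for the genotype comparisons held exactly the same values. Levels per sample, fold changes and their tests are not analysed here. What follows describes the pooled level of each gene over all genotypes and both conditions, without an SD, because the spread between samples does not enter a pooled mean. These levels carry no information on an effect of genotype or of heat.

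The pooled means covered 55801 gene identifiers on 12 chromosomes and summed to 11614572 normalised counts. Of these genes, 40831 lay above 0 and 14970 (26.8%) were listed at 0. Among the genes above 0 the median was 15.9 normalised counts, 2109 genes reached 1000 and 140 reached 10000. The 10 highest genes held 5.24% of the total, and the 100 highest held 21.2%. The values are not divided by gene length, so a longer gene has a higher value at the same number of transcripts.

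The lowest values fell on 30 distinct steps, each the worth of 1 read in 1 library, which matches the number of samples. The steps give size factors (relative library depth) from 0.551 to 1.64. A gap separated 20 libraries at 1.09 to 1.64 from 10 libraries at 0.551 to 0.741. One read was worth between 0.0203 and 0.0605 normalised counts. A gene listed at 0 therefore has no read in any library, and 3 reads in the shallowest library, the limit that a count of 0 allows, would have given 0.181. This limit covers counting error only.

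**Figure D1:**
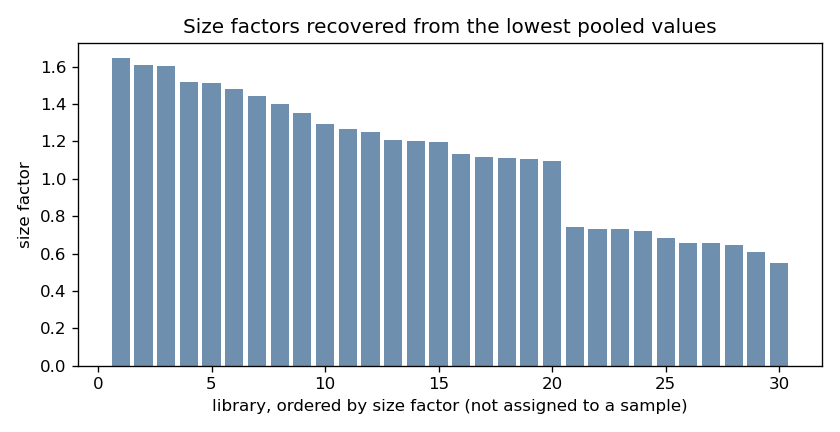
Size factor of each of the 30 libraries, recovered from the lowest pooled values and ordered from high to low; the bars are libraries, which are not assigned to samples or groups. The 20 libraries on the left lie between 1.09 and 1.64 and the 10 on the right between 0.551 and 0.741.

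Both manipulated genes, paired with their loci from general knowledge and not found by symbol in the reference, were read in the pooled libraries. ONAC127 (LOC_Os11g31340, chromosome 11) had a pooled mean of 593 normalised counts, higher than 93.6% of all genes. ONAC129 (LOC_Os11g31380, chromosome 11) had 1309 normalised counts, higher than 97.1% of all genes and 2.21 times the value of ONAC127. These means include the overexpressing lines of both genes, so they are not wild-type levels, and they give no check of the genotype labels.

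Genes for seed storage proteins stood among the highest in the profile. The 10 glutelin genes, which encode the main storage proteins of the rice endosperm, had a median of 27917 normalised counts and held 2.72% of the total. GluC1 ranked 3 of all genes with 66984 normalised counts, GluA1 ranked 6 with 61910 and GluA2 ranked 10 with 47812. GluA3 had 42080, GluB2 had 35496 and GluB7 had 20338. GluB5, GluB4 and GluD1 had 14680, 13081 and 8056, and GluB1 was the lowest of the list at 5622. The GluB genes are close copies of each other, and reads they share may have been split or lost in counting, so their single values are uncertain. The highest value of the whole profile, 77413, belonged to LOC_Os05g41970. This locus was listed beforehand as the alpha-globulin gene, but the reference table places that symbol elsewhere on the chromosome, so it was kept out of the list.

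The regulator genes known to act in endosperm filling were high as well, with a median of 4744 normalised counts over 8 genes. RPBF, an activator of storage protein genes, had 20001, and NAC26 and NAC20, which act on starch and storage protein genes, had 12059 and 9389. NF-YB1 had 4991, NF-YC12 had 4497, bZIP58 had 2229 and FLO2 had 1684. RSR1, a repressor of starch synthesis genes, was the lowest of the 8 at 98.8 normalised counts, so that RPBF stood 202 times above it. Of the 8, only NF-YB1 and RSR1 were found by symbol in the reference, and the others, RPBF among them, rest on general knowledge.

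All 25 starch synthesis genes measured were above 0, and 13 of them reached 1000 normalised counts. The highest were BT1-1, a transporter of ADP-glucose into the amyloplast, with 48215 normalised counts and GBSSI, the granule-bound starch synthase that makes amylose, with 39906. Branching enzyme BEI followed with 29480, soluble starch synthase SSIIa with 20453, branching enzyme BEIIb with 15782 and AGPL2, a large subunit of ADP-glucose pyrophosphorylase, with 12909. Some members of the same enzyme family lay far apart, in pairs chosen after their values were seen. Of the genes in the pairs below, only GBSSI and AGPS2 were found by symbol in the reference. The identities of the others rest on general knowledge alone. GBSSI had 117 times the value of GBSSII, BEIIb 52.1 times that of BEIIa, SSIIa 565 times that of SSIIb, SSIIIa 40.4 times that of SSIIIb and AGPL2 26.8 times that of AGPL1. Other pairs were closer, with the small subunit AGPS2 at 4.22 times AGPS1 and BEI at 1.87 times BEIIb. ISA1 had 5106 normalised counts and ISA2 had 3301. The lowest members were AGPL4 at 18.1, SSIIb at 36.2 and SSIVa at 47.3 normalised counts.

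Genes that bring in and cleave sucrose spanned a wider range, and 7 of the 17 listed reached 1000 normalised counts. Sucrose synthase SUS3 led with 28727 normalised counts, against 7836 for SUS2, 3003 for SUS4 and 1248 for SUS1. Among the SWEET sugar exporters, SWEET11 had 7668, SWEET15 had 1719, SWEET4 had 671 and SWEET14 had 435. The sucrose transporter SUT1 had 2203, which was 4.68 times the value of SUT2 (471) and 15.6 times that of SUT4 (141), and SUT3 was listed at 0. Of the cell wall invertases, CIN2 (also named GIF1, a grain filling gene) had 648 normalised counts, 104 times the value of CIN1 and 286 times that of CIN3. The monosaccharide transporters MST6 and MST4 had 208 and 84.0.

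Chaperone genes were abundant in the pool, in which hot and normal growth are averaged. The 9 heat shock protein genes had a median of 7286 normalised counts. BiP1, the chaperone of the endoplasmic reticulum, had 20781, Hsp101, a disaggregase, had 17417, and the Hsp90 family genes Hsp82A and Hsp90-1 had 14986 and 11181. The small heat shock proteins Hsp18, Hsp16.9A, Hsp17.7 and Hsp16.9B had 7286, 4911, 2297 and 1455, and ClpB-M had 997. Hsp16.9A and Hsp16.9B lie side by side and are close copies, so their split of reads is uncertain. The 8 heat shock transcription factor genes had a median of 1477, from 5895 for HsfB2c and 4973 for HsfA2a down to 88.0 for HsfA7. Between them, HsfB2b had 2552, HsfA2c had 2097, HsfB2a had 857, HsfA2d had 299.9 and HsfA2e had 247. In the list of folding genes of the endoplasmic reticulum, PDIL1-1, a protein disulfide isomerase, had 20924 and the regulator bZIP50 had 2198, beside BiP1.

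Markers of the other tissues of the caryopsis were also present. The 6 photosynthesis genes, which mark the green fruit coat, had a median of 3365 normalised counts, with LHCB1, of the light-harvesting complex, at 10679. The other light-harvesting genes LHCB2, LHCB1b and LHCB3 had 5688, 4669 and 1975, and RBCS3 and RBCS2, of the carbon-fixing enzyme Rubisco, had 2061 and 1352. None of these 6 was found by symbol in the reference. Of the embryo and aleurone markers, the oleosins Ole16 and Ole18, which coat oil bodies, had 24670 and 21160. LEA3 had 2124, Em had 1663 and the dehydrin Rab16A had 722. MADS29, a regulator of nucellus breakdown, had 109.6. OSH1, a marker of the embryo's shoot meristem, had 15.3, just below the median of 15.9 over all genes above 0. The 7 alpha-amylases, which degrade starch, had a median of 19.1, but RAmy3E alone had 3354, which was 22.7 times the next highest, RAmy3B, at 148. RAmy3D had 44.2 and RAmy2A had 19.1. RAmy1A, RAmy3A and RAmy3F each lay below 1 normalised count, at 0.574, 0.780 and 0.516.

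Of the genes known as targets of ONAC127 and ONAC129 from the study, which were chosen on these or related samples, 5 were examined and all 5 were read. HCI1 was not examined, because its locus was in doubt. The transcription factor gene bHLH144 had 9842 normalised counts, the sugar transporters SWEET4 and MST6 had 671 and 208, the ethylene response factor EATB had 317 and the calmodulin-like MSR2 had 64.5. EATB and MSR2 were also the only members with a fixed locus in the lists of ethylene response factors and of calcium signalling.

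Set against 10000 random lists of the same size drawn from the genes above 0, 10 of the 11 lists with at least 3 members had a median above the 95th percentile. None of the random lists had a median as high as the storage protein, starch, sugar, endosperm regulator, heat shock protein and heat shock factor lists did. The photosynthesis and folding lists lay at percentile 99.99, and the embryo and aleurone list at percentile 99.97. The study's targets lay at percentile 97.56, but at percentile 87.1 against lists drawn from genes of at least 10 normalised counts. The alpha-amylase list lay at percentile 53.7, and at percentile 0.37 against the latter. That low percentile follows in part from the filter, so it does not show that the alpha-amylases were unusually low. RAmy1A, RAmy3A and RAmy3F stayed in the list, but no gene below 10 normalised counts could be drawn. All these percentiles describe the pooled profile, and genes are not replicates. The lists hold named genes chosen from general knowledge, whereas the genes above 0 include 3700 with 1 read over all libraries. High percentiles were therefore likely in advance and are not independent support for the levels given above. The lists also overlap, since BiP1, SWEET4 and MST6 stand in more than 1.

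**Figure D2:**
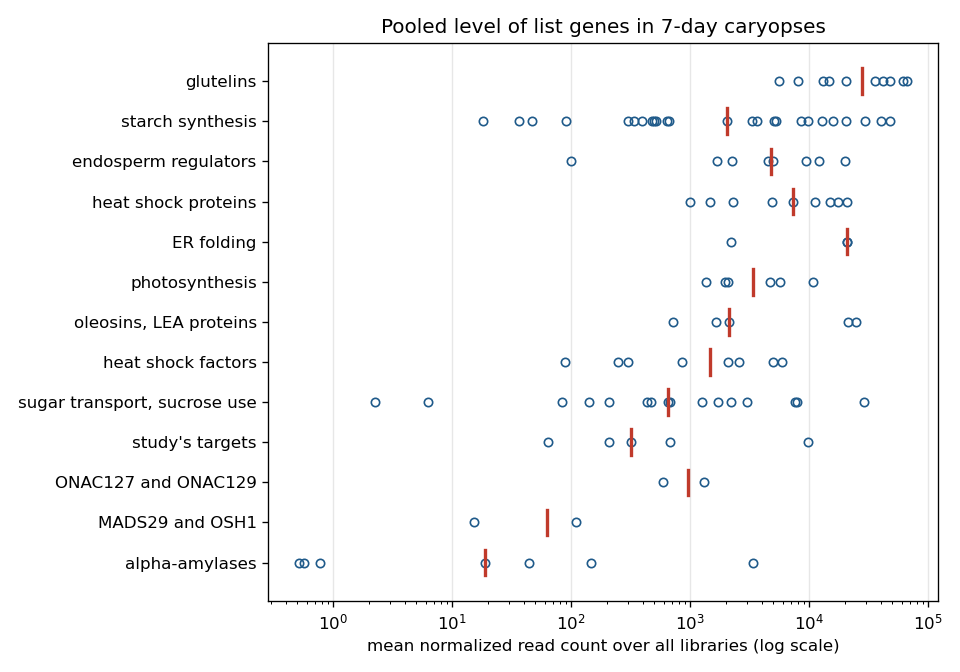
Pooled mean normalised read count (log scale) of each gene above 0 in 13 gene lists; circles are genes and vertical bars are the list medians, in which SUT3 counts as 0. The glutelin list lies highest, with a median of 27917, and the alpha-amylase list lowest, with a median of 19.1 and RAmy3E far to its right at 3354.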

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

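The alternatives below were all chosen after seeing the data. The settings fixed before the data were examined (other normalisation, tool, filter, fitted samples, fold threshold, pseudocount, adjusted p threshold, and leaving out replicates) were not run, because they need values per sample or comparison tables. No paired analysis was possible because the pooled column carries no replicate numbers. With at least 10 normalised counts required, 22056 genes counted as detected in place of 40831, and with at least 1, 28428. Without the GluB genes the storage protein list held 1.95% of the total in place of 2.72%, and with LOC_Os05g41970 added it held 3.39%. With all genes as background 10 of 11 lists lay above the 95th percentile. With genes of at least 10 as background 9 did, since the study's targets then lay at percentile 87.1. The alpha-amylases lay at percentiles 80.2 and 0.37 under these backgrounds. The value of 0.37 follows in part from the filter, which kept RAmy1A, RAmy3A and RAmy3F in the list but no such gene in the background. The number of libraries found was 30 whether steps were told apart within 1e-11, 1e-12 or 1e-10. This is a weak check, because even the closest steps, 0.022 and 0.02201, differ by far more than these. The upper bound on the values searched for steps was not varied. Closed sets of 3 libraries, defined among the other observations, numbered 1 with genes of 2 to 3 reads in place of 2, and the cause was not tested. A pooled mean limits every value here: its spread between samples cannot be stated, and a change in 1 group is diluted over all 30 libraries.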

Other observations

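The tests in this part were all chosen after the result was seen. The share of genes listed at 0 differed between chromosomes, from 18.6% on chromosome 3 to 34.3% on chromosome 11. Chromosome 3, with 5568 gene identifiers, held 16.5% of the total of normalised counts, and chromosome 12, with 4014, held 4.03%.

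The 3933 genes with 2 to 5 reads over all libraries show which libraries share rare transcripts. The 10 libraries below the gap in size factor shared such genes more often with each other than chance gives: their mean relative co-detection (shared genes over those expected, scaled to 1 over all pairs) was 1.41, against 1.01 among the 20 others and 0.90 between both sets. In 1000 permutations of the reads between libraries that kept the reads per gene and per library, the highest value was 1.12 (one-sided permutation p = 0.001, the smallest they can give). The permutations treat reads as independent molecules and cover counting error only. With the reads of a gene in a library counted once, so that copies of a molecule do not add, the value was 1.40 and the highest of 1000 permutations was 1.14. Both values argue against the reads per library alone, depth alone, as the cause. The 10 libraries are not a multiple of the 3 samples per group, so the gap does not run between whole groups. By the design no genotype or condition holds exactly 10 libraries, so this is a matter of counting and not a test of a cause. A shared batch, and a genotype or condition shared by only some of the 10, stay open. They cannot be told apart, because 0 columns hold a single sample.

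The design has groups of 3, so a candidate explanation for uneven sharing is replicate groups of 3 that share rare transcripts. Closed sets of 3, in which each library has the other 2 as its closest partners, numbered 2 and held 6 of the 30 libraries. The permutations gave 0.069 such sets on average (one-sided permutation p = 0.004), but their highest number was also 2, and this p too covers counting error only. Both sets lay above the gap in size factor. The permutations did not keep the uneven sharing across the gap described above, so this p is not a test of sets of 3 alone. The count of 2 sets did not exceed every permutation, so by itself it did not settle depth alone. The co-detection of the libraries below the gap, given above, argues against depth alone for those libraries. Replicate groups of 3 were not settled either, since 24 libraries lay outside closed sets. In simulated data with groups of 3 planted, 8 such sets were found, and 0 without them. The planted effect had a chosen size and the simulated size factors had no gap. The 8 sets are therefore not the number that replicate groups would give in these data.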
